A study of Mus musculus with 10 samples.

How the data were processed

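The deposited file held 1 value per gene symbol and library, which the column names of the file assign to the 10 samples, and all 10 were used. The values are log2(TPM + 1) as deposited by the authors, a unit inferred here from the values themselves, since the lowest value was 0 and the values taken back to TPM summed to 946103 to 954463 per library. Per the submitters' processing notes, kallisto and limma were used with the genome build GRCm38, while their versions and roles are not given in the sources used here. The file had 30320 lines of values, of which 30319 carried a gene symbol and 7254 genes were listed at 0 in every library. The line without a symbol held 0.00544% to 0.0108% of TPM per library and was not used. Depth could not be judged, because TPM values keep no read numbers.

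Libraries were grouped by the genotype and diet of their labels into WT_LFD (n = 2), Null_LFD (n = 3), WT_HFD (n = 2) and Null_HFD (n = 3). Gene symbols were matched to GENCODE M21 (GRCm38) for biotype and coordinates, which succeeded for 28447 symbols and for 16154 of the genes tested, 14384 of them protein coding. At most 2.34% of the tested genes had identical values in any 2 libraries.

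Genes with at least 1 TPM in at least 2 libraries were tested, 16932 in all. The log2(TPM + 1) values were fitted with limma (3.58.1, R 4.3.3) as 4 group means, with empirical Bayes variances that follow mean expression and 6 residual degrees of freedom. The 7 comparisons were null minus wild type averaged over the diets, within the low-fat diet and within the high-fat diet, high-fat minus low-fat averaged over the genotypes, within wild type and within null, and the interaction. All gene tests were two-sided, p values were adjusted over the genes of each comparison by the Benjamini-Hochberg method, and a gene was called at an adjusted p of at most 0.05. Differences on the log2(TPM + 1) scale understate fold changes of genes with low values.

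A set of 25 gene lists with 515 entries, 514 of them present as symbols, was written before the data were examined. The lists cover mature adipocyte, fatty acid synthesis, cholesterol synthesis, thermogenic fat, collagens and structural matrix, matrix proteases and crosslinking, fibroblast and adipocyte progenitor, macrophage, lymph node, mammary luminal and basal epithelium, skeletal muscle, endothelium, Schwann cell, mTOR and insulin signalling, mTORC1 and ATF4 targets, ribosomal protein, oxidative phosphorylation, integrin and focal adhesion, TGF-beta, type I interferon, immediate early, circadian clock and cell cycle genes, and genes flanking Fap. Each list was compared with all other genes by limma's camera with a preset correlation between genes of 0.01 and again with the correlation estimated from the data, adjusted over the lists of a comparison. The rotation test fry asks whether the genes of a list move on balance one way, and its mixed form whether they change in either direction, and neither compares the list with other genes. List members were also adjusted over the list alone, and, for the 2 averaged comparisons, the mean of each list was tested by exact two-sided permutation of the libraries within diets or within genotypes.

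Named genes followed a rule fixed before the data were examined. It takes the 10 largest rises and falls among called genes with a mean of at least 5 TPM in a group compared and no overlap between the groups, passing over predicted genes, then up to 4 members of each called list by smallest p, and the 5 genes with the smallest p where fewer than 5 pass. Mki67, Rps12, Metap1d, Serping1 and the genes in the closing section that the rule does not name were chosen after their values were seen. The text gives only a part of the genes that the rule names, and the others are not reported here. Means with SD are given for Fap, and values of each library or their range for other genes.

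The procedure was tested on simulated data with 5 draws of 16932 genes, 200 of them changed. The changed genes were drawn only from the more highly expressed ones, so recovery was not measured for tested genes with low values. Of changes of 1, 2 and 4 on the log2 scale it recovered 49.6%, 86.9% and 98.2% for the averaged genotype comparison, 44.5%, 89% and 98.5% for the averaged diet comparison, 19.1%, 69.3% and 95.8% for genotype within the low-fat diet, 12.5%, 63% and 91.5% for diet within wild type, 33.7%, 72.8% and 97% for diet within null, and 2.09%, 43.6% and 85.2% for the interaction. On average 4.6 to 9.2 unchanged genes were called. In 20 simulated draws, camera called 18 lists that had been shifted by 0.5, and 2 other lists. Simulated genes varied independently of each other, so these draws do not show how camera performs on lists whose genes vary together. Other groupings of the real libraries within diets called a median of 9 lists. Genotype within the high-fat diet has the same numbers of libraries as within the low-fat diet and was not simulated separately. Figures were made with Python 3.11.15.

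Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a filter of 5 TPM, median-of-ratios scaling, quantile normalization, empirical Bayes without trend and in robust form, sample weights from arrayWeights, a fit of only the groups compared, the replicate number as a block, the lymph node or the luminal list mean as a covariate, and leaving out each library. Added after seeing the data were leaving out both lymph node-rich libraries, protein-coding genes only, TPM rescaled without mitochondrially encoded genes, and the exact permutation of list means.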

Results

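Total RNA from the inguinal subcutaneous mammary fat pads of female FVB mice was sequenced after depletion of ribosomal RNA. The mice were wild type or null for Fap, the gene of fibroblast activation protein, a membrane serine protease of activated fibroblasts. They were fed ingredient-matched diets with 10% or 60% of calories from fat between 12 and 30 weeks of age. The 10 libraries form 4 groups, with 2 wild-type low-fat (WT_LFD), 3 null low-fat (Null_LFD), 2 wild-type high-fat (WT_HFD) and 3 null high-fat (Null_HFD) samples, which the series describes as biological replicates. The title of the series frames the question as the part FAP plays in the formation of adipocytes and in mTOR signalling that depends on the extracellular matrix.

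Between 14574 and 15700 genes reached 1 TPM in a library. TPM values keep no record of read numbers, so the depth behind each value is unknown. Mitochondrially encoded transcripts took from 3.19% (Null_HFD 3) to 13.2% (WT_LFD 2) of all TPM.

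WT_HFD 2 and Null_HFD 3 stood apart from the other libraries. The principal component with the most variance (37%) placed them at 61.8 and 113, against -31.6 to -14.1 for the other 8 libraries, and their median correlations with the other libraries, taken across genes, were 0.911 and 0.855 against 0.931 to 0.954. Their lymph node marker list, which holds B cell, T cell and lymph node stroma genes, lay 3.24 and 4.67 above the mean of the 10 libraries on the log2 scale, against -1.31 to -0.693 in the others. Their skeletal muscle list lay at -2.9 and -3.84. Mammary epithelium also varied, as the luminal list ran from -1.83 (Null_HFD 3) and -1.24 (WT_LFD 2) to 1.04 and 1.44 (Null_LFD 1 and 2). The cell cycle list lay at 2.58 in Null_LFD 3 and between -0.725 and 0.769 in the other 9 libraries.

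**Figure D1:**
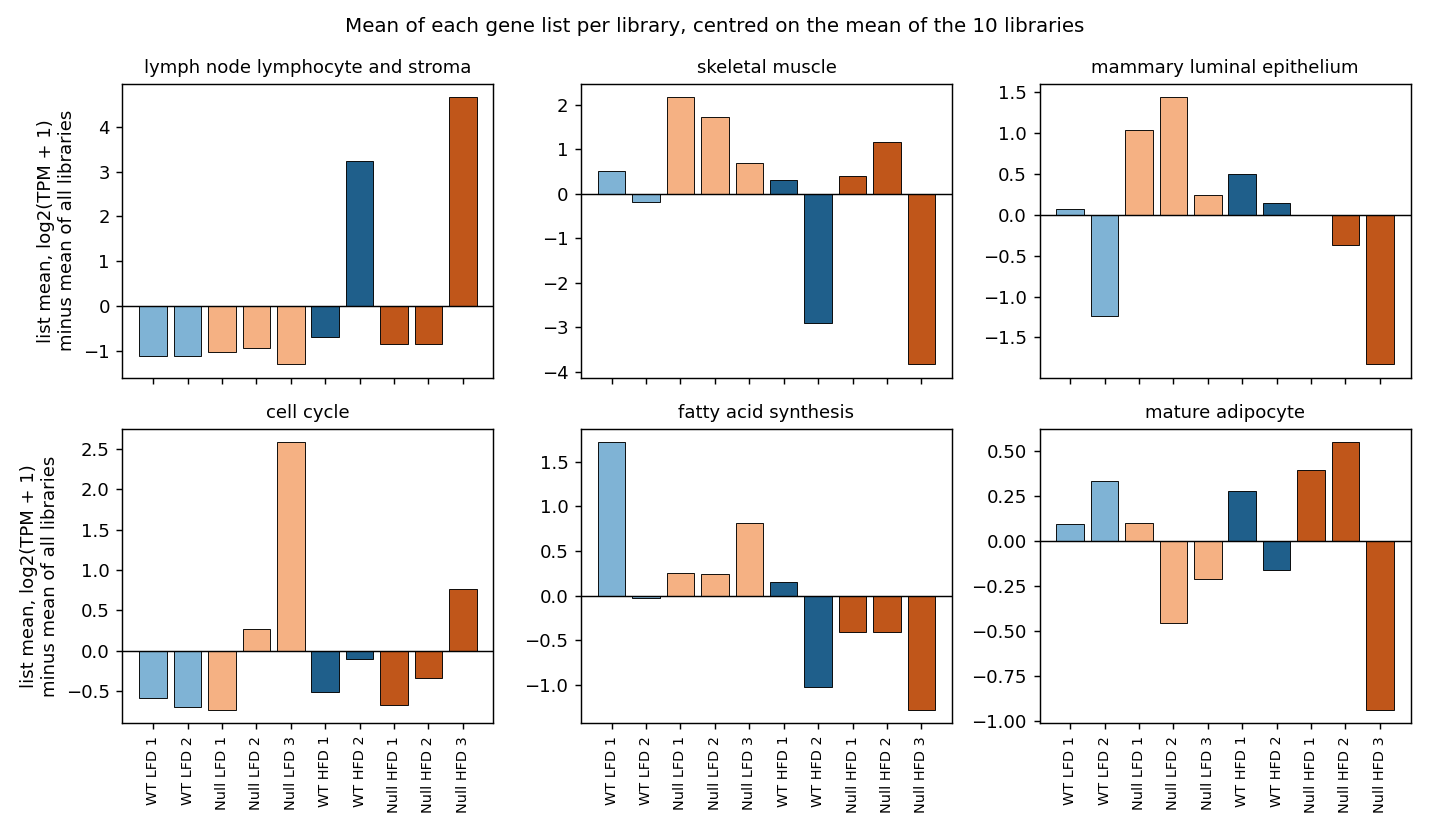
Mean log2(TPM + 1) of 6 gene lists in each of the 10 libraries (x axis), shown as the difference from the mean of all 10 libraries (y axis, log2 units), with bars coloured by group. The lymph node list reaches 3.24 in WT_HFD 2 and 4.67 in Null_HFD 3, and the cell cycle list 2.58 in Null_LFD 3.

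Fap, the targeted gene, lies on the minus strand of chromosome 2, 62500943 to 62574075 (GRCm38, ENSMUSG00000000392.17). On the low-fat diet its transcript measured 42.3 ± 4.33 TPM (SD, n = 2; libraries 45.4 and 39.3) in wild-type pads and 19.7 ± 2.31 TPM (SD, n = 3; 18.4, 22.4 and 18.3) in null pads. On the high-fat diet it measured 53.2 ± 22.0 TPM (SD, n = 2; 68.8 and 37.6) in wild-type pads and 29.1 ± 8.32 TPM (SD, n = 3; 26.7, 38.4 and 22.3) in null pads. Fap was lower in null pads by 0.94 on the log2(TPM + 1) scale (log2 difference -0.94, SE 0.21). As a single gene chosen in advance, Fap had a limma p of 0.0015 before adjustment over all genes. Its adjusted p was 0.686, so the difference did not pass the test over all genes. The library labelled Null_HFD 2 (38.4 TPM) lay above the library labelled WT_HFD 2 (37.6 TPM). The transcript remained present in all 6 null libraries, and the labels do not state which part of the gene is disrupted, so a gene-level TPM is a partial check of the genotype labels. Fap did not pass within the low-fat diet (log2 difference -1.07, SE 0.30, adjusted p = 0.949), within the high-fat diet (-0.82, SE 0.30, adjusted p = 1) or between the diets (0.39, SE 0.21, adjusted p = 0.542). Without WT_HFD 1 the high-fat difference was -0.395, and without WT_HFD 2 it was -1.25.

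**Figure D2:**
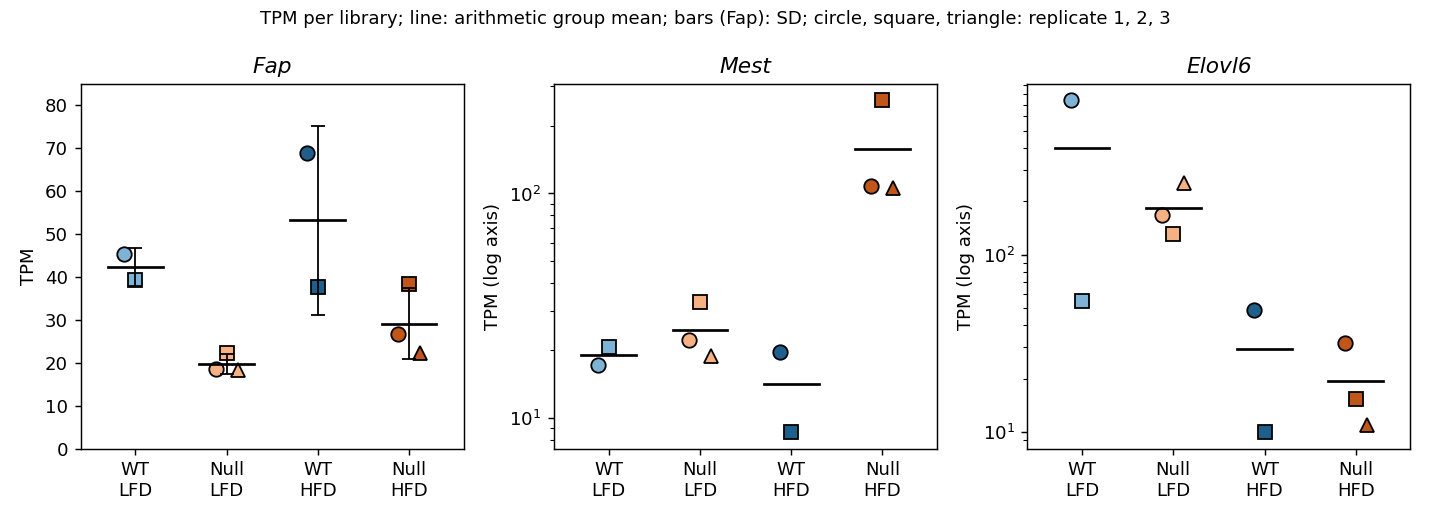
TPM of Fap, Mest and Elovl6 in each library by group (x axis), with a linear y axis for Fap and log y axes for Mest and Elovl6. Lines are arithmetic group means, bars for Fap are SD, and Mest measures 106 to 260 TPM in the 3 Null_HFD libraries against 8.66 to 32.7 TPM in the other 7.

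The median difference over all 16932 genes tested was not 0 in several comparisons. It was 0.146 between null and wild type on the low-fat diet, 0.197 between the diets in wild type, 0.11 between the diets on average and -0.131 in the interaction, and median-of-ratios scaling moved these to 0.0128, 0.0148, -0.00547 and 0.000282. Gene differences are given on the deposited scale, and gene list tests compare a list with all other genes, so they are relative to that shift.

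Genotype was compared over both diets to ask which transcripts followed the loss of Fap, in 6 null against 4 wild-type libraries. Relative to other genes, macrophage and immediate early transcripts lay higher in null pads, while fatty acid synthesis and mature adipocyte transcripts lay lower. The macrophage list averaged 0.411 higher (20 of 22 members higher, camera adjusted p = 0.00097, adjusted p = 0.805 with an estimated correlation). Trem2, a lipid-sensing receptor of macrophages, measured 2.38 to 4.60 TPM in wild-type and 5.17 to 17.4 TPM in null libraries (log2 difference 1.09, SE 0.33), and Atp6v0d2, a lysosomal proton pump subunit, differed by 1.00 (SE 0.45). The immediate early list averaged 0.472 higher (13 of 14 members higher, camera adjusted p = 0.00097, adjusted p = 0.805 with an estimated correlation), with Ier3 at 3.54 to 4.99 TPM in wild-type and 5.56 to 10.2 TPM in null libraries.

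Fatty acid synthesis genes averaged -0.335 in null pads (19 of 20 members lower, camera adjusted p = 0.000375, adjusted p = 0.805 with an estimated correlation), among them Acacb, an acetyl-CoA carboxylase, at -1.04 (SE 0.41). This call ended without WT_LFD 1 (mean 0.102) and without WT_HFD 1 (-0.0412), and the mean moved to -0.772 without WT_LFD 2, -0.629 without WT_HFD 2 and -0.19 without Null_HFD 3. Mature adipocyte genes averaged -0.228 (18 of 24 lower, camera adjusted p = 0.00097, adjusted p = 0.805 with an estimated correlation), with Cfd, the adipokine adipsin, at -1.40 (SE 0.60) and the lipid droplet protein gene Plin1 at 0.41 (SE 0.24). Null_HFD 3, the library with the highest lymph node list, had the lowest adipocyte list (-0.935 from the mean), and the call ended without it (mean 0.00713) and without WT_HFD 1 (-0.118), while the mean was -0.364 without Null_HFD 2. Collagen and structural matrix genes averaged 0.31 (20 of 26 higher, camera adjusted p = 0.01, adjusted p = 0.805 with an estimated correlation). Elastin (Eln, 1.19, SE 0.38) was among the higher members and decorin (Dcn, -0.52, SE 0.22) among the lower ones, and the call ended without any 1 of WT_LFD 1, Null_LFD 3, WT_HFD 2, Null_HFD 1 or Null_HFD 2 (means 0.283, 0.231, 0.32, 0.269 and 0.239).

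The mTOR and insulin signalling list was called lower than other genes (camera adjusted p = 0.0477, adjusted p = 0.805 with an estimated correlation), although 13 members were higher and 13 lower and the mean was -0.0223. Its members with the smallest p were Pik3r1, a regulatory subunit of phosphoinositide 3-kinase (-0.66, SE 0.20), and Rps6kb1, the S6 kinase downstream of mTOR complex 1 (-0.33, SE 0.12). The call ended without any 1 of WT_LFD 2, Null_LFD 2, Null_LFD 3, WT_HFD 1, WT_HFD 2 or Null_HFD 3 (means 0.00591, -0.0289, 0.0109, -0.0829, 0.0384 and 0.0131), and the mean was -0.0505, -0.0488 and -0.06 without WT_LFD 1, Null_LFD 1 and Null_HFD 2. Without both lymph node-rich libraries the mean was 0.0738, and the call held in 12 of 25 alternative settings. The list of mTORC1 and ATF4 targets averaged 0.162 and was not called (camera adjusted p = 0.449).

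Cell cycle genes averaged 0.785 higher in null pads (20 of 20, camera adjusted p = 0.000815, adjusted p = 0.805 with an estimated correlation). Null_LFD 3 carried most of this, with Mki67, a marker of dividing cells, at 79.5 TPM against 2.68 to 18.6 TPM elsewhere, and without it the call ended (mean 0.318). The cell cycle call also ended without both lymph node-rich libraries (0.673), with sample weights and with the replicate number as a block (0.106). Ribosomal protein genes averaged 0.282 (30 of 32 higher, camera adjusted p = 0.0272, adjusted p = 0.805 with an estimated correlation). This ribosomal call ended without WT_LFD 1, Null_LFD 2, Null_LFD 3, WT_HFD 1 or Null_HFD 3 (means 0.328, 0.259, 0.236, 0.155 and 0.0676). It ended without both lymph node-rich libraries (0.195), with sample weights and with the block (0.0216) as well. Thermogenic fat genes averaged -0.336 (13 of 15 lower, camera adjusted p = 0.012, adjusted p = 0.805 with an estimated correlation). They turned to 0.205 without WT_HFD 1 and lost the call without WT_LFD 2 (-0.0455), Null_LFD 2 (-0.19) or Null_HFD 3 (0.071), with means of -0.626, -0.519, -0.876 and -0.743 without WT_LFD 1, Null_LFD 1, WT_HFD 2 and Null_HFD 1. Skeletal muscle genes averaged 0.946 (15 of 15 higher, camera adjusted p = 0.0477, adjusted p = 0.805 with an estimated correlation). The muscle call ended without WT_LFD 1, WT_LFD 2, Null_LFD 1, Null_LFD 2, WT_HFD 2, Null_HFD 1 or Null_HFD 2 (means 1.12, 0.77, 0.784, 0.897, 0.148, 0.657 and 0.465) and rested at 1.74 without WT_HFD 1 and 1.72 without Null_HFD 3.

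No single gene passed in the averaged genotype comparison, where limma called 0 of 16932 genes, and 709 had an unadjusted p under 0.05 (491 higher, 218 lower) against 847 expected by chance. With median-of-ratios scaling that split was 365 higher of 716. No member of the 10 called lists passed over all genes or adjusted over the list alone, where 1 member of the type I interferon list passed. Among the genes with the smallest p, the olfactory receptor gene Olfr1033 on chromosome 2 was listed at 0 in all 4 wild-type libraries and at 2.79 to 7.24 TPM in the 6 null libraries (adjusted p = 0.111), and Hax1, a mitochondrial anti-apoptotic gene, differed by 2.85 (SE 0.39, adjusted p = 0.158). The other 3 were pseudogenes by annotation or by name, whose values are uncertain because near-identical copies share reads, led by Gm10123 (at most 0.0113 TPM in wild-type libraries and 10.9 to 308 TPM in null libraries, adjusted p = 0.11). Leaving out WT_LFD 1 gave 2 calls, and leaving out WT_LFD 2, Null_LFD 1, Null_LFD 3 or Null_HFD 2 gave 1 call each.

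Genes whose 4 wild-type and 6 null libraries did not overlap numbered 156 of 16932, where chance gives 0.952% of genes or 161. They were unevenly placed, a comparison chosen after their values were seen. On chromosome 2, which carries Fap, 27 of 1336 tested genes (2.02%) did not overlap, against 0.777% elsewhere (Fisher's exact test, p = 4.03e-05, adjusted p = 0.000806 over 20 chromosomes). Genes are not independent replicates, since neighbours and copies can vary together. Metap1d, a mitochondrial methionine aminopeptidase gene at 71453276 to 71525194 on that chromosome, measured 13.2 to 17.4 TPM in wild-type and 25.5 to 35.2 TPM in null libraries, and Serping1, the complement C1 inhibitor gene, 274 to 402 TPM and 133 to 257 TPM. The list of genes flanking Fap, fixed in advance, averaged -0.00311 and was not called (camera adjusted p = 0.222). Camera looks for a shared direction, so a list mean near 0 cannot by itself decide whether its members changed in both directions. The mixed form of fry, which looks for change in either direction, passed no list in this comparison (lowest adjusted p 0.592). Metap1d, higher in null libraries, and Serping1, lower, are not members of the flanking list.

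**Figure D3:**
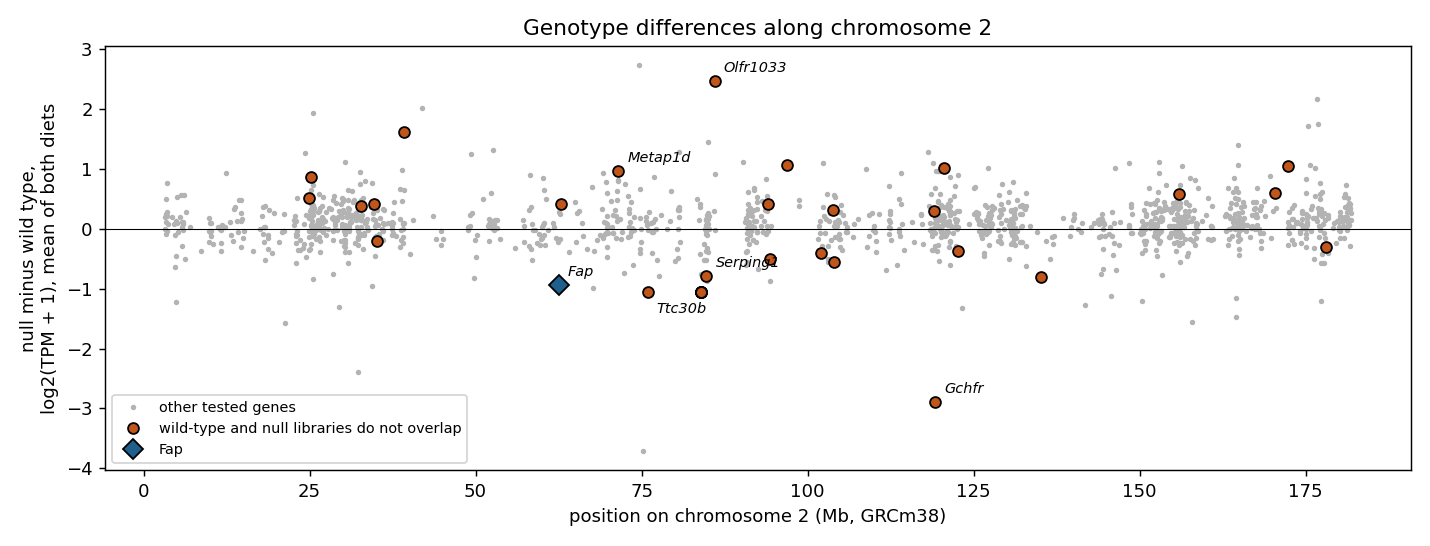
Difference between null and wild type (y axis, log2(TPM + 1), mean of both diets) of each tested gene on chromosome 2 by its position (x axis, Mb, GRCm38). Orange points are genes whose wild-type and null libraries do not overlap (2.02% of tested genes on this chromosome against 0.777% elsewhere), grey points are the other tested genes, and the blue diamond is Fap.

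Genotype within the low-fat diet compared 3 null with 2 wild-type libraries. Relative to other genes, luminal epithelial transcripts as a list lay higher in null pads, and cholesterol synthesis and mature adipocyte transcripts lay lower. The luminal list averaged 1.49 higher (19 of 20 members higher, camera adjusted p = 7.71e-07, adjusted p = 0.67 with an estimated correlation). Csn3, which encodes kappa-casein, measured 223 and 63.1 TPM in wild-type and 1306, 1059 and 358 TPM in null libraries (log2 difference 2.73, SE 0.70), and Elf5, a transcription factor of the secretory luminal lineage, 29.9 and 17.2 against 83.8, 119 and 54.1 TPM (1.80, SE 0.51). Without WT_LFD 2, the low-fat library with the lowest luminal list, the mean was 0.843 and the call held. The skeletal muscle list was not called (camera adjusted p = 0.0667). It averaged 1.35 higher (15 of 15 members), at 2.17, 1.71 and 0.678 in null against 0.518 and -0.187 in wild-type libraries, which leaves a difference in tissue content open. Cholesterol synthesis genes averaged -0.511 (17 of 20 lower, camera adjusted p = 2.2e-09, adjusted p = 0.67 with an estimated correlation), including Insig1, a sterol-sensing retention protein gene (-1.32, SE 0.49). Their mean was -0.202 without WT_LFD 1 and -0.821 without WT_LFD 2. Mature adipocyte genes averaged -0.4 (20 of 24 lower, camera adjusted p = 1.59e-06, adjusted p = 0.67 with an estimated correlation), with the fatty acid transporter gene Cd36 at -0.80 (SE 0.45).

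Basal epithelial genes also averaged higher on the low-fat diet in null pads (0.65, 13 of 13, camera adjusted p = 0.00428, adjusted p = 0.67 with an estimated correlation), with Trp63, a transcription factor of basal epithelium, at 1.45 (SE 0.51). That call ended without WT_LFD 2 (0.208) or Null_LFD 2 (0.541), and the mean was 1.09 without WT_LFD 1. Ribosomal protein genes averaged 0.541 (31 of 32 higher, camera adjusted p = 0.000257, adjusted p = 0.739 with an estimated correlation). Macrophage genes averaged 0.54 (19 of 22 higher, camera adjusted p = 0.00633, adjusted p = 0.67 with an estimated correlation), with Cd14, a lipopolysaccharide co-receptor, at 18.6 and 15.6 TPM in wild-type against 90.4, 108 and 33.4 TPM in null libraries, and the call ended without WT_LFD 1 (0.541) or Null_LFD 2 (0.449). Cd14 was the 1 member that passed when adjusted over the list alone, and no member passed over all genes. Cell cycle genes averaged 1.34 (20 of 20 higher, camera adjusted p = 1.75e-05, adjusted p = 0.67 with an estimated correlation), which ended at 0.409 without Null_LFD 3 and was 2.06 without Null_LFD 1. Immediate early genes averaged 0.503 (13 of 14 higher, camera adjusted p = 0.0369, adjusted p = 0.67 with an estimated correlation), and ended without WT_LFD 2 (0.259), Null_LFD 1 (0.454) or Null_LFD 2 (0.385).

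Fatty acid synthesis genes averaged -0.409 on the low-fat diet (18 of 20 lower, camera adjusted p = 1.75e-05, adjusted p = 0.67 with an estimated correlation), but the direction rested on WT_LFD 1, without which the mean was 0.464, against -1.28 without WT_LFD 2. Pnpla3, a lipid droplet acyltransferase and lipase gene, measured 341 and 179 TPM in wild-type and 76.6 to 104 TPM in null libraries (-1.45, SE 0.37). Thermogenic fat genes averaged -0.763 (14 of 15 lower, camera adjusted p = 3.09e-05, adjusted p = 0.67 with an estimated correlation), ended at -0.182 without WT_LFD 2, and averaged -1.34 without WT_LFD 1 and -0.471 without Null_LFD 2. Nuclear genes of oxidative phosphorylation averaged -0.176 (21 of 23 lower, camera adjusted p = 3.09e-05, adjusted p = 0.67 with an estimated correlation), ended at -0.014 without Null_LFD 2, and averaged -0.0522, -0.3 and -0.27 without WT_LFD 1, WT_LFD 2 and Null_LFD 1. Endothelial genes averaged -0.0823 (12 of 15 lower, camera adjusted p = 0.0401, adjusted p = 0.739 with an estimated correlation), ended without WT_LFD 1 (0.0496) or Null_LFD 3 (0.0458), and averaged -0.214 without WT_LFD 2 and -0.173 without Null_LFD 2. In this comparison limma called 0 genes, 750 had an unadjusted p under 0.05 (615 higher, and 394 of 733 with median-of-ratios scaling), and 1 gene was called without WT_LFD 1. Hax1 (4.26, SE 0.55, adjusted p = 0.208), Car2, a carbonic anhydrase gene at 9.54 and 7.20 TPM against 23.6 to 39.9 TPM (1.88, SE 0.31, adjusted p = 0.48), and Arhgap8 (1.72, SE 0.28, adjusted p = 0.48) were among the smallest p, with the pseudogenes Fau-ps1 (adjusted p = 0.207) and Rps15a-ps6.

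Genotype within the high-fat diet again compared 3 null with 2 wild-type libraries. Here luminal epithelial transcripts lay lower in null pads and cholesterol synthesis transcripts higher. The luminal list averaged -1.06 (20 of 20 members lower, camera adjusted p = 2.18e-08, adjusted p = 0.92 with an estimated correlation), with Elf5 at 82.4 and 72.2 TPM in wild-type and 58.5, 34.2 and 15.5 TPM in null libraries, and it averaged -0.507 without Null_HFD 3. Cholesterol synthesis genes averaged 0.522 (18 of 20 higher, camera adjusted p = 1.02e-05, adjusted p = 0.92 with an estimated correlation). Hmgcs1, the cytosolic HMG-CoA synthase gene, measured 120 and 59.2 TPM in wild-type and 180, 292 and 180 TPM in null libraries (1.32, SE 0.40), and the list averaged 0.342 without Null_HFD 2. Collagen and matrix genes averaged 0.289 (18 of 26 higher, camera adjusted p = 0.0114, adjusted p = 0.98 with an estimated correlation), among them Col15a1 (1.36, SE 0.45) and Sparc (0.89, SE 0.34), with Dcn at -0.75 (SE 0.31). The matrix call ended without WT_HFD 2 (0.311), Null_HFD 1 (0.208) or Null_HFD 2 (0.148), and the mean was 0.511 without Null_HFD 3. Immediate early genes averaged 0.442 (11 of 14 higher, camera adjusted p = 0.0114, adjusted p = 0.92 with an estimated correlation), ended without WT_HFD 1 (0.203) or Null_HFD 2 (0.348), and averaged 0.681 without WT_HFD 2. No member of these 4 lists passed over all genes or adjusted over the list alone.

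Both genes that limma called within the high-fat diet were lower in null pads and both are processed pseudogenes. Rps12l1 (chromosome 7, 56014016 to 56014414, GRCm38), a copy of a ribosomal protein gene, measured 1524 and 2544 TPM in wild-type and at most 2.79 TPM in the 3 null libraries (log2 difference -9.74, SE 0.92, adjusted p = 0.0334). Rps12 itself was listed at 0 in all 10 libraries, so the division of reads between such copies is uncertain. Gm18588 (chromosome 3, 68902267 to 68902758) measured 15.0 and 48.5 TPM in wild-type libraries and was listed at 0, 0 and 0.521 TPM in null libraries (-4.61, SE 0.49, adjusted p = 0.0439). Both calls ended without Null_LFD 1, Null_LFD 2, WT_HFD 2, Null_HFD 1 or Null_HFD 3, which left 0 called genes, and without Null_LFD 3 or Null_HFD 2, which left 1 other gene each. Rps12l1 kept its call without WT_LFD 1 or WT_LFD 2, and Gm18588 without WT_HFD 1, where 3 genes were called. Of the protein-coding genes, Mest, an imprinted gene active in expanding fat (chromosome 6, 30723547 to 30748465), had the smallest p, at 108, 260 and 106 TPM in the Null_HFD libraries against 19.7 and 8.66 TPM in WT_HFD (3.36, SE 0.45, adjusted p = 0.128). In all, 647 genes had an unadjusted p under 0.05, 318 of them higher (368 of 722 with median-of-ratios scaling).

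Diet was compared over both genotypes to ask how the high-fat diet altered the pads, in 5 high-fat against 5 low-fat libraries. Fatty acid synthesis transcripts lay lower on the high-fat diet for all 20 members (mean -1.21, camera adjusted p = 6.14e-15, adjusted p = 0.787 with an estimated correlation). Elovl6, a fatty acid elongase gene (chromosome 3, 129532355 to 129638495), measured 54.8 to 740 TPM in low-fat and 10.0 to 48.8 TPM in high-fat libraries (log2 difference -3.18, SE 0.71). Fasn, the fatty acid synthase gene, measured 581 to 3006 TPM and 72.5 to 741 TPM (-2.53, SE 0.68), and the acetyl-CoA carboxylase gene Acaca differed by -2.18 (SE 0.66). Adjusted over the list alone 10 members passed, and 0 passed over all genes. The list mean was -0.771 without WT_LFD 1, and -0.769 without both lymph node-rich libraries, and kept its camera call each time. An exact permutation test of the list mean within genotypes gave p = 0.0333 (smallest possible 0.0167), or 0.278 adjusted over the 25 lists.

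Lymph node markers averaged 2.24 higher on the high-fat diet (21 of 21 members higher, camera adjusted p = 5e-06, adjusted p = 0.791 with an estimated correlation). The difference came mainly from WT_HFD 2 and Null_HFD 3. Ccl21a, a lymph node stroma chemokine, measured 298 and 748 TPM there, 3.08 to 15.5 TPM in the other 3 high-fat libraries and 0.479 to 2.26 TPM in the low-fat libraries. The list averaged 1.26 without WT_HFD 2, 1.32 without Null_HFD 3 and 0.337 without both. Skeletal muscle genes averaged -1.87 (15 of 15 lower, camera adjusted p = 3.44e-10, adjusted p = 0.787 with an estimated correlation), with means of -1.08 without WT_HFD 2, -1.1 without Null_HFD 3 and -0.306 without both. With the lymph node list as a covariate the diet calls ended for muscle (-0.0384), thermogenic (0.0562) and luminal genes (0.154), and 4 others held, for fatty acid synthesis, cholesterol synthesis, oxidative phosphorylation and cell cycle genes. Thermogenic fat genes averaged -0.999 (14 of 15 lower, camera adjusted p = 1.98e-06, adjusted p = 0.791 with an estimated correlation), with Cidea, a lipid droplet protein gene of brown and beige fat, at -1.70 (SE 0.71). Their mean was -1.54 without WT_HFD 1, -0.459 without WT_HFD 2 and -0.593 without Null_HFD 3, and the call ended at -0.0523 without both lymph node-rich libraries.

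Nuclear genes of oxidative phosphorylation averaged -0.353 on the high-fat diet (23 of 23 lower, camera adjusted p = 1.01e-11, adjusted p = 0.787 with an estimated correlation), with Ndufb5, a complex I subunit gene, at 260 to 386 TPM in low-fat and 164 to 285 TPM in high-fat libraries, and the mean was -0.142 without both lymph node-rich libraries. Cholesterol synthesis genes averaged -0.373 (16 of 20 lower, camera adjusted p = 9.87e-07, adjusted p = 0.787 with an estimated correlation), -0.218 without WT_LFD 1, and 1 member, Insig1 (-1.48, SE 0.34), passed when adjusted over the list alone. The fall was confined to wild type, at 0.751 and 0.132 from the mean of the 10 libraries on the low-fat and -0.403 and -0.493 on the high-fat diet. Null libraries overlapped and averaged higher on the high-fat diet (-0.226, -0.297 and 0.314, then -0.352, 0.436 and 0.138). Luminal genes averaged -0.366 (18 of 20 lower, camera adjusted p = 0.000238, adjusted p = 0.791 with an estimated correlation). Wild type went the other way, with the luminal list at 0.0647 and -1.24 on the low-fat and 0.5 and 0.146 on the high-fat diet. The luminal call ended at -0.0411 without WT_LFD 1 and at -0.00341 without both lymph node-rich libraries, and the mean was -0.691, -0.233, -0.549 and -0.0919 without WT_LFD 2, Null_LFD 2, Null_HFD 1 and Null_HFD 3. Cell cycle genes averaged -0.225 (17 of 20 lower, camera adjusted p = 0.0276, adjusted p = 0.878 with an estimated correlation) but averaged 0.243 without Null_LFD 3, lost the call without WT_LFD 2 (-0.253), WT_HFD 1 (-0.126), Null_HFD 1 (-0.0766) or Null_HFD 2 (-0.161), and lay at -0.583 and -0.437 without Null_LFD 1 and Null_HFD 3. In wild type the cell cycle list lay higher on the high-fat diet (-0.581 and -0.695, then -0.503 and -0.105). The mature adipocyte list had a mean difference of 0.0171 and a median of -0.0428 and was not called (camera adjusted p = 0.425). The mTOR and insulin signalling list averaged 0.247 and was not called (camera adjusted p = 0.263), with 2 members passing when adjusted over the list alone.

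Between the diets limma called 0 genes, and 1641 had an unadjusted p under 0.05 against 847 expected (1245 higher, and 629 of 1448 with median-of-ratios scaling). With the lymph node list as a covariate 1132 genes had such a p. Without WT_HFD 2, a fit that leaves 1 wild-type high-fat library, fewer genes than expected had one. Ppp1r10, a nuclear regulator of a protein phosphatase, had the smallest p, at 25.3 to 43.9 TPM in the 5 low-fat and 58.9 to 75.2 TPM in the 5 high-fat libraries (log2 difference 1.02, SE 0.13, adjusted p = 0.296). Lctl, a lactase-like gene (-1.69, SE 0.28), and Inpp5b, an inositol polyphosphate phosphatase gene (0.99, SE 0.17), came next among protein-coding genes, each with an adjusted p of 0.513. Leaving out WT_LFD 2, WT_HFD 1 or Null_HFD 2 gave 1 called gene, as did leaving out both lymph node-rich libraries.

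Diet within wild type compared 2 high-fat with 2 low-fat libraries, of which WT_HFD 2 was rich in lymph node markers. Cholesterol and fatty acid synthesis transcripts lay lower on the high-fat diet. Cholesterol synthesis genes averaged -0.89 (18 of 20 lower, camera adjusted p = 2.67e-15, adjusted p = 0.548 with an estimated correlation), with Insig1 at 545 and 390 TPM on the low-fat and 133 and 54.1 TPM on the high-fat diet (-2.43, SE 0.53) and Msmo1, a sterol oxidase gene, at -1.45 (SE 0.35). These 2 members passed when adjusted over the list alone, and the mean was -0.58 without WT_LFD 1. Fatty acid synthesis genes averaged -1.28 (18 of 20 lower, 1 adjusted over the list alone, camera adjusted p = 3.39e-13, adjusted p = 0.575 with an estimated correlation), and their mean moved to -0.408 without WT_LFD 1, -2.15 without WT_LFD 2 and -0.694 without WT_HFD 2. Oxidative phosphorylation genes averaged -0.484 (23 of 23 lower, camera adjusted p = 2.73e-13, adjusted p = 0.82 with an estimated correlation) and -0.253 without WT_HFD 2.

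The other wild-type diet calls leaned on WT_HFD 2. Without it the calls ended for lymph node genes (2.39, then 0.422), skeletal muscle genes (-1.47, then 0.129), thermogenic genes (-1.43, then -0.346), ribosomal protein genes (0.597, then 0.343) and mature adipocyte genes (-0.156, then 0.0625). Their camera adjusted p values were 0.00255, 1.08e-05, 1.08e-07, 0.0038 and 0.0186, and with an estimated correlation the adjusted p was 0.82 for thermogenic genes and 0.839 for the other 4. Without WT_HFD 1 the means were 4.36 for lymph node, -3.06 for muscle, -2.51 for thermogenic and -0.374 for adipocyte genes. Thermogenic genes averaged -0.846 without WT_LFD 2, and adipocyte genes -0.276 without WT_LFD 1 and, with the call ended, -0.035 without WT_LFD 2. The adipocyte list split into 11 higher and 13 lower members, with Agpat2, an enzyme of triglyceride synthesis, at -1.74 (SE 0.57). No gene was called by limma (0 of 16932), 950 had an unadjusted p under 0.05 (718 higher, and 351 of 983 with median-of-ratios scaling), and 1 and 2 genes were called without WT_LFD 2 and WT_HFD 1. Ppp1r10 measured 25.3 and 28.8 TPM on the low-fat and 67.9 and 70.6 TPM on the high-fat diet (1.33, SE 0.19, adjusted p = 0.586).

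Diet within the null genotype compared 3 high-fat with 3 low-fat libraries. Luminal epithelial transcripts lay lower on the high-fat diet for all 20 members (mean -1.64, camera adjusted p = 1.23e-15, adjusted p = 0.865 with an estimated correlation). Epcam, an epithelial adhesion gene, measured 106, 174 and 175 TPM on the low-fat and 63.3, 75.9 and 22.6 TPM on the high-fat diet (-1.61, SE 0.46), and Csn3 differed by -2.12 (SE 0.62). Adjusted over the list alone 11 members passed, against 0 over all genes, and the mean was -1.09 without Null_HFD 3. Fatty acid synthesis genes averaged -1.13 (18 of 20 lower, camera adjusted p = 3.53e-07, adjusted p = 0.865 with an estimated correlation), with Elovl6 at 131 to 252 TPM on the low-fat and at most 31.6 TPM on the high-fat diet (-3.25, SE 0.90). Skeletal muscle genes averaged -2.28 (15 of 15 lower, camera adjusted p = 4.61e-08, adjusted p = 0.865 with an estimated correlation) and -0.742 without Null_HFD 3. Lymph node genes averaged 2.09 (21 of 21 higher, camera adjusted p = 2.92e-05, adjusted p = 0.865 with an estimated correlation), and the call ended at 0.253 without Null_HFD 3. With the luminal list as a covariate the fatty acid synthesis call ended (-0.239), muscle (0.839), basal (0.204) and oxidative phosphorylation genes (0.0836) turned without a call, and lymph node genes turned to lower than other genes (-0.947).

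Cell cycle genes averaged -0.784 in null pads on the high-fat diet (20 of 20 lower, camera adjusted p = 0.000245, adjusted p = 0.865 with an estimated correlation), but 0.151 without Null_LFD 3, with -1.5, -0.488 and -1.21 without Null_LFD 1, Null_HFD 1 and Null_HFD 3. Basal epithelial genes averaged -0.517 (9 of 13 lower, camera adjusted p = 0.00326, adjusted p = 0.865 with an estimated correlation), ended at -0.19 without Null_HFD 3 and at -0.408 without Null_LFD 2, and averaged -0.829 without Null_HFD 2. Oxidative phosphorylation genes averaged -0.222 (20 of 23 lower, camera adjusted p = 0.00132, adjusted p = 0.865 with an estimated correlation), ended at -0.128 without Null_LFD 1 and at -0.0308 without Null_HFD 3, and averaged -0.384 and -0.349 without Null_LFD 2 and Null_HFD 1. Endothelial genes averaged 0.268 (12 of 15 higher, camera adjusted p = 0.035, adjusted p = 0.865 with an estimated correlation), with the receptor gene Tie1 at 0.53 (SE 0.22), and ended without Null_LFD 3 (0.14), WT_HFD 1 (0.268), Null_HFD 1 (0.259) or Null_HFD 2 (0.0369), with 0.509 without Null_HFD 3. The 1 gene that limma called was the pseudogene Gm18588, lower on the high-fat diet (21.1, 37.3 and 25.6 TPM against 0, 0 and 0.521 TPM, log2 difference -4.62, SE 0.44, adjusted p = 0.0338), and its call ended without any 1 of the 6 null libraries, which gave 0 called genes without Null_LFD 1, Null_LFD 2, Null_LFD 3 or Null_HFD 3, 2 other genes without Null_HFD 1 and 1 other without Null_HFD 2. Without WT_LFD 1 or WT_LFD 2 the count was 2, with Gm18588 in it. Supt5, a transcription elongation factor gene, measured at most 0.278 TPM on the low-fat and 18.8, 7.79 and 26.0 TPM on the high-fat diet (adjusted p = 0.0918), and Lsr, a lipoprotein receptor gene, differed by -1.68 (SE 0.27, adjusted p = 0.396). An unadjusted p under 0.05 was reached by 1129 genes, 603 of them higher (547 of 1225 with median-of-ratios scaling).

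The interaction asked whether the diet difference differed between the genotypes. Luminal epithelial genes had a lower diet difference in null than in wild-type pads (-2.55, 20 of 20 members lower, camera adjusted p = 3.72e-14, adjusted p = 0.538 with an estimated correlation). Csn3 (-4.00, SE 0.99) and Elf5 (-3.06, SE 0.72) were among the 8 members that passed when adjusted over the list alone, against 0 over all genes. Cholesterol synthesis genes had a higher diet difference in null pads (1.03, 19 of 20 members higher, camera adjusted p = 3.66e-14, adjusted p = 0.538 with an estimated correlation), with Hmgcs1 at 1.84 (SE 0.56). Both of these lists kept their camera call without any single library, with means of -3.2 to -1.9 and 0.724 to 1.34. The luminal list is a marker of mammary epithelium and ran from -1.83 (Null_HFD 3) to 1.44 (Null_LFD 2) among the libraries. A difference in tissue content is therefore left open for it. Lep, the leptin gene, measured 387 and 507 TPM in WT_LFD, 277 and 865 TPM in WT_HFD, 133 to 346 TPM in Null_LFD and 990 to 1492 TPM in Null_HFD libraries (2.12, SE 0.76). It belongs to the mature adipocyte list, which averaged 0.345 (19 of 24 members higher, camera adjusted p = 0.00268, adjusted p = 0.905 with an estimated correlation).

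The adipocyte interaction ended without WT_LFD 2 (0.225), Null_LFD 2 (0.213), WT_HFD 2 (0.127), Null_HFD 1 (0.149) or Null_HFD 2 (0.0721), and was 0.564 and 0.815 without WT_HFD 1 and Null_HFD 3. Oxidative phosphorylation genes averaged 0.262 (23 of 23 higher, camera adjusted p = 0.000452, adjusted p = 0.905 with an estimated correlation). Their interaction ended without Null_LFD 2 (0.0996), WT_HFD 2 (0.0315) or Null_HFD 1 (0.134), and were 0.138, 0.492 and 0.453 without WT_LFD 1, WT_HFD 1 and Null_HFD 3. Thermogenic genes averaged 0.854 (12 of 15 higher, camera adjusted p = 0.00366, adjusted p = 0.905 with an estimated correlation). They lost the call without WT_LFD 2 (0.274), Null_LFD 2 (0.562), WT_HFD 2 (-0.227) or Null_HFD 1 (0.0392), and were 1.43, 1.93 and 1.67 without WT_LFD 1, WT_HFD 1 and Null_HFD 3. Ribosomal protein genes averaged -0.519 (31 of 32 lower, camera adjusted p = 0.012, adjusted p = 0.905 with an estimated correlation). The ribosomal call ended without Null_LFD 3 (-0.427), WT_HFD 2 (-0.265), Null_HFD 1 (-0.321) or Null_HFD 2 (-0.288), and were -0.947 without Null_HFD 3. Cell cycle genes averaged -1.12 (20 of 20 lower, camera adjusted p = 0.0181, adjusted p = 0.905 with an estimated correlation). The cell cycle call ended without WT_LFD 1 (-1.18), Null_LFD 3 (-0.183), WT_HFD 1 (-1.32), WT_HFD 2 (-0.92), Null_HFD 1 (-0.822) or Null_HFD 2 (-0.991), and were -1.83 without Null_LFD 1. No gene passed the interaction test (limma, 0 of 16932), 701 had an unadjusted p under 0.05 (182 higher, and 340 of 750 with median-of-ratios scaling), and 2 and 1 genes were called without WT_LFD 2 and Null_HFD 2. The protein-coding genes with the smallest p were Tor1aip1, an inner nuclear membrane gene (-2.83, SE 0.44), and Dusp23, a phosphatase gene (-2.74, SE 0.44), each with an adjusted p of 0.53.

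Several fixed lists were called in none of the 7 comparisons with either correlation. Matrix protease and crosslinking genes averaged 0.197 between genotypes and 0.141 between diets (lowest camera adjusted p over the 7 comparisons 0.186), fibroblast and progenitor genes 0.0266 and 0.071 (0.311), and Schwann cell genes 0.0608 and -0.0877 (0.289). Integrin and focal adhesion genes averaged 0.173 and 0.199 (0.0642), TGF-beta pathway genes 0.0858 and 0.284 (0.136), type I interferon genes 0.00444 and 0.0861 (0.449), circadian clock genes -0.023 and 0.197 (0.105), and mTORC1 and ATF4 targets 0.162 and 0.136 (0.449). Genes flanking Fap averaged 0.136 between diets (0.138).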

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

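The permutation test of fatty acid synthesis against adipocyte genes, the tests of lymph node vessel genes, the tests that left out both lymph node-rich libraries, and the split tests of unadjusted p and of gene lists were chosen only after the result was seen.

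The 7 gene lists called in the interaction were marked because their diet difference differed between the genotype groups. Null minus wild type, the diet difference was 1.03 for cholesterol synthesis, -2.55 for luminal epithelium, 0.262 for oxidative phosphorylation, 0.345 for mature adipocyte, 0.854 for thermogenic fat, -0.519 for ribosomal protein and -1.12 for cell cycle genes. Only the cholesterol and luminal calls held without any single library, and for the luminal list a difference in tissue content was left open. The lowest adjusted p with an estimated correlation was 0.538, so none passed that test.

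The high lymph node list of the high-fat diet may reflect pieces of lymph node in WT_HFD 2 and Null_HFD 3, as the inguinal pad encloses a lymph node. If so, genes of lymph node vessels outside the list should also be highest there, and 3 of 3 were. Glycam1 measured 674 and 1264 TPM in those libraries and at most 49.4 TPM elsewhere, while Madcam1 (3.12 to 3.13 against at most 2.47 TPM) and Chst4 (1.16 and 6.47 against 0 TPM) were low. A diet difference of this size was not present in every high-fat mouse, as the list difference was 0.337 without both libraries (exact permutation p = 0.0333, the smallest possible of 30 splits). Both libraries were left out for their high values of this same list, so the fall describes the values and tests no cause. The smaller remaining difference leaves a diet effect on lymphocytes open.

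Lower fatty acid synthesis on the high-fat diet could come from less adipocyte RNA, but the values spoke against this as far as the mature adipocyte list measures that RNA. Members of that list can themselves differ with diet, as Lep did in null pads, so it is an imperfect measure. Relative to the mature adipocyte list the difference was -1.22 in all 10 libraries (exact permutation p = 0.0333), while the adipocyte list itself differed by 0.0171 (exact permutation p = 0.967). In null pads the diets did not overlap by this measure. In wild type it rested on WT_LFD 1, whose synthesis list lay 1.72 above the mean of the 10 libraries. WT_LFD 2 (synthesis -0.0318, adipocyte 0.335) lay below WT_HFD 1 (0.148 and 0.277). Without both lymph node-rich libraries the first difference was -1.13 (exact permutation p = 0.167, 30 splits), and the adipocyte list lay higher on the high-fat diet, the opposite of what less adipocyte RNA needs. The lymph node-rich libraries might carry part of it, since the difference of the synthesis list alone was -0.769 without them (exact permutation p = 0.233), which leaves this open. A lower rate of fatty acid synthesis under dietary fat is a candidate explanation that transcripts alone do not test.

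Splits of the libraries into groups of the same sizes were compared, with the real split counted among them. For the averaged genotype comparison, chance cannot be excluded for the genes with an unadjusted p under 0.05, where 46 of 100 splits had at least the real 709 (highest other 4154), or for the called lists, where 47 of 100 had at least the real 10 (highest other 14). The number of genes called by limma was 0, which all 100 splits reach by definition, so it says nothing about chance. The highest other split called 1053 genes and put WT_HFD 2, Null_HFD 3, Null_LFD 2 and Null_LFD 3 together, which points to structure of the samples.

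For the averaged diet comparison, chance cannot be excluded either, as 3 of 60 splits had at least the real 1641 genes with an unadjusted p under 0.05 (highest other 2077) and 40 of 60 at least the real 8 lists (highest other 13). Its 0 genes called by limma are reached by all 60 splits by definition (highest other 3) and test nothing. Diet within null has only 10 splits, the real one included, too few for a share under 0.05. At least the real 1 called gene was found in 2 of them (highest other 1), the real 1129 genes with an unadjusted p under 0.05 in 3 (highest other 1616), and the real 8 lists in 10 (highest other 14).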

How the results depend on the processing

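The alternatives were fixed before the data were examined, except that leaving out both lymph node-rich libraries, testing protein-coding genes only, rescaling without mitochondrial genes and permuting list means were chosen after seeing the data. Of the tests in this part, those 4 were chosen only after the result was seen. Fap stayed lower in null under every setting, at -1.16 to -0.732 without single libraries and -1.07 to -0.836 otherwise.

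Counts of called genes stayed small and changed with the setting, and the cause was not tested. A pseudocount of 0.1 called 3 genes for averaged genotype, 5 for genotype on the low-fat diet, 1 for genotype on the high-fat diet and 0 for diet in null. Without the filter, which raised the genes tested to 23065, the counts were 15, 2 and 18 for the same genotype comparisons, 3 for averaged diet, 5 for diet in wild type, 0 for diet in null and 3 for the interaction. Without the trend they were 5 and 1 for averaged and low-fat genotype, 2 for diet in wild type and 0 for diet in null. Sample weights gave 2, 2 and 2 for averaged genotype, low-fat genotype and diet in null. Fitting only the groups compared gave 1, 1 and 2 for low-fat genotype, high-fat genotype and diet in null. For high-fat genotype, the 1 gene called with that fit or with the pseudocount of 0.1 was neither Rps12l1 nor Gm18588. The lymph node covariate gave 3 for diet in null, and the luminal covariate 1 for high-fat genotype and 0 for diet in null. Both lymph node-rich libraries left out gave 0 for high-fat genotype, 1 for averaged diet and 0 for diet in null, and protein-coding genes only gave 0 and 0 for high-fat genotype and diet in null, since the called genes are pseudogenes. Without single libraries the counts ran 0 to 2 for averaged genotype, 0 to 1 for low-fat and 0 to 3 for high-fat genotype, 0 to 1 for averaged diet, 0 to 2 for diet in wild type, 0 to 2 for diet in null and 0 to 2 for the interaction.

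With the replicate block, diet in null had 3 called genes and high-fat genotype 12 called lists, and the ribosomal list of averaged genotype turned relative to other genes at 0.0216. Whether equal replicate numbers pair the samples stayed open. Deviations from the group means had a median correlation of 0.0245 in the 13 such pairs against -0.0022 in 24 others. In groups of 2 libraries the deviations mirror each other, so these pairs are not independent and cannot exclude pairing.

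Called lists numbered 0 in all 7 comparisons with the estimated correlation and with fry (lowest adjusted p 0.436), and in averaged genotype and averaged diet, where it was run, with exact permutation (lowest adjusted p 0.278). Exact permutation can give no p below 0.01 for averaged genotype and 0.0167 for averaged diet. A list at that limit passes adjustment over 25 lists only if several others reach it too, so the permutation result says little about single lists. High-fat genotype called 11 lists with sample weights, 13 with the luminal covariate and 7 without both lymph node-rich libraries, and the interaction 11 with sample weights and 11 with the luminal covariate. Without single libraries the lists numbered 6 to 11, 8 to 14 and 4 to 12 for averaged, low-fat and high-fat genotype, 7 to 10 for averaged diet, 5 to 9 for diet in wild type, 7 to 10 for diet in null and 2 to 12 for the interaction. Where an arm kept 1 library, it was assumed to vary like the other groups.

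Of 1449 list values under alternatives, 1231 kept their call and their direction relative to other genes. Another 203 lost the call and 15 reversed that direction, and the cause was not tested. These values include fits without a library of a group that was not compared. There the list mean cannot change, which raises the share that kept its call. A kept call is not a stable mean, as muscle genes for diet in null moved from -2.28 to -0.742 without Null_HFD 3. With the lymph node covariate, diet in wild type reversed for mature adipocyte (0.359) and muscle (0.492) genes, and for ribosomal genes (0.113) relative to other genes only. With the luminal covariate, basal genes reversed for low-fat genotype (-0.00653), and lymph node (-0.947), basal (0.204), muscle (0.839) and oxidative phosphorylation (0.0836) genes for diet in null. Leave-one-out reversed fatty acid synthesis in low-fat genotype (-1.28 to 0.464), cell cycle in averaged diet (-0.583 to 0.243) and in null diet (-1.5 to 0.151), and in averaged genotype thermogenic genes (-0.876 to 0.205). In averaged genotype the muscle (0.148 to 1.74) and ribosomal (0.0676 to 0.409) means stayed positive, and only their direction relative to other genes turned, at their lowest values. Of 6520 values of named genes, 6432 kept their sign and their called or uncalled state. Another 35 lost a call, 37 gained a call and 16 turned sign without a call. Most named genes were called under neither setting, so these numbers say little about how stable their values were.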

Other observations

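Milk protein transcripts spread widely among libraries. Csn2, the beta-casein gene, measured 717 and 594 TPM in Null_LFD 1 and 2, 89.0 TPM in Null_LFD 3, 79.4 and 7.12 TPM in WT_LFD, 273 and 60.7 TPM in WT_HFD, and 152, 36.2 and 0 TPM in Null_HFD libraries, and Csn1s2a ran from 9.28 to 2764 TPM. Null_LFD 3 had 298 TPM of the histone gene Hist1h2ah against at most 50.3 TPM elsewhere, and 48.6 TPM of the keratin gene Krt15 against at most 9.34 TPM. Gchfr on chromosome 2 (119167773 to 119172390, GRCm38), a regulator of tetrahydrobiopterin synthesis, measured 30.9, 22.2, 31.9 and 12.3 TPM in wild-type libraries, 11.8 TPM in Null_HFD 1 and 1.09 to 1.91 TPM in the other 5 null libraries. These genes were chosen after their values were seen.

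All tests of genes that do not overlap between the genotypes were chosen only after the result was seen. Donor-strain sequence that stayed linked to Fap when the null line was bred may explain part of the 156 such genes. Within 25 Mb of Fap 7 of 223 tested genes did not overlap (3.14%, 0.849% elsewhere, Fisher's exact p = 0.00361), which fits that hypothesis, although 2 of 92 within 10 Mb gave p = 0.194 and 20 of 1113 on chromosome 2 beyond 25 Mb gave p = 0.00173. Shared reads of near-identical copies were not told apart, since pseudogenes and predicted genes made up 16.9% of such genes and 13.3% of others (Fisher's exact p = 0.213). The labels give no strain history, so genome variants were not examined.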
